A study of Solanum lycopersicum with 4 samples.

How the data were processed

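Leaves of tomato (Solanum lycopersicum) were digested to protoplasts, and single-cell 3′-end libraries were made from them in droplets with a version 3 kit, per the labels' protocols. The labels name 4 samples with 1 sample each: healthy plants of 30 days, and plants infected with ToCV, tomato chlorosis virus, of 10, 30 and 40 days. No group has a replicate sample. The series describes its purpose as sampling healthy and infected plants.

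The deposited data are 1 combined matrix of UMI counts, that is, whole-number counts of distinct RNA molecules per gene and barcode, with no normalization by the authors. The matrix holds 34075 gene identifiers, 44867 barcodes and 46330391 entries above 0. Each of the 3 files of this matrix (counts, barcodes, identifiers) was present in 2 copies, 1 of them carrying the title of the 10-day infected sample in its name. The copies were identical byte for byte in all 3 pairs and were counted once. The submitters' processing notes name Cell Ranger 3.1.0, STAR and Seurat 3.1.1, while the header of the deposited count matrix names Cell Ranger 5.0.0. The genome build and the gene annotation are not given in the sources used here.

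Barcodes end in a number from 1 to 5. These 5 sets of barcodes are called libraries 1 to 5 below. Nothing in the labels or files ties a suffix to a labelled sample, and there are 5 suffixes for 4 labelled samples. No cell was therefore assigned to a healthy or infected plant or to an age, and no comparison between groups was made. Values are given for each library, or as a range and median over the libraries, without a test and without p-values. The 5 libraries are not replicates of a group.

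The files give gene identifiers and no gene names. The reference gene table used here (41476 rows) matched 0 of the 34075 identifiers, so no gene is named. Gene groups were instead lists of identifiers written down before the data were examined, from prior knowledge of the tomato gene numbering. Their membership was not checked against an annotation. The lists cover pathogenesis-related proteins (17 identifiers), RNA silencing (20), jasmonate (20), salicylate (4), ethylene (2), light harvesting (7), carbon fixation by the Calvin cycle (3), chlorophyll synthesis (8), chlorophyll breakdown (6), reactive oxygen enzymes (3), sugar metabolism (2) and housekeeping genes (7). Cell type lists cover mesophyll (10), epidermis (9), guard cell (4), trichome (7), phloem (4) and dividing cells (2). Lists for WRKY factors, heat shock proteins, senescence and autophagy, ribosomal proteins and xylem had been written as description patterns with 0 identifiers and were not evaluated.

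Barcodes with at least 500 UMIs and 300 detected genes were kept. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. It marked 5 cells, 0.0116% of those kept, which is under the 0.5% below which the caller was taken not to have worked, so no cell was removed as a doublet. Counts were scaled to 10000 per cell and log-transformed. For clustering, 2000 variable genes were ranked within each library and combined, scaled within library and reduced to 30 principal components. Neighbours were taken equally from each library, 5 from each, and clusters were found with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5 and seed 1. Of the 122 listed identifiers in the matrix, 39 were among the variable genes.

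Counts were summed per library, and per library and cluster, and expressed as CPM, counts scaled to a total of 1000000. Log2 ratios compare a cluster with all other cells of the same library, after adding 1 CPM to both, in libraries with at least 50 cells of the cluster. A gene was called 2-fold or more higher in a cluster if this held in every such library and its level in the cluster was 50 CPM or more. For members of the lists this call was made without the 50 CPM, among members with a mean of 1 CPM or more over the libraries. A cluster was named after a cell type if that type had the most identifiers among its top 50 genes, ranked by the lowest ratio over libraries, and at least 3 of its identifiers were 2-fold or more higher in every library. The number 50 was chosen after the data had been seen. Genes named in the text were chosen by a rule fixed before: the leading genes of a cluster by that ranking, members of the lists, and the 10 genes of widest range over libraries, the last in the closing section only. Because the files do not pair identifiers with names, few identifiers are printed.

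The median log2 ratio of a list's members with a mean of 1 CPM or more was placed among 10000 random lists of the same size matched on mean level. The correlation of a list's members was described over 37 sums of counts, 1 for each library and cluster with at least 50 cells, on log2 levels from which each gene's mean over the clusters of a library had been subtracted. Both describe these libraries and are not tests. Intervals are 95% exact Poisson intervals for sums of counts and 95% exact binomial (Clopper-Pearson) intervals for shares. They cover counting error only. A count of 0 was read as an upper limit of 3 counts.

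The calculation of ratios was tested on simulated data for cluster 5, drawn from the real library means. In it, 200 genes were changed by known folds among 2709 genes with a mean of 50 CPM or more over the libraries. Of 25 genes raised 2.5-fold, 84% were called in every library, against 96% of 25 raised 4-fold and 100% of 25 raised 8-fold, while 0 of 25 raised 1.5-fold and 0 of 2509 unchanged genes were called. Changes in genes below 50 CPM or in other clusters were not simulated. These rates therefore do not cover list members at lower levels or the small clusters. Clustering recovered 3 simulated cell types in 3000 cells with an adjusted Rand index of 1. These types were drawn from the profiles of clusters 3, 5 and 6, with 1500 UMIs per cell and equal cell numbers in each library. Clusters that bordered cluster 3 were not simulated, so this does not test that boundary. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

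Alternatives fixed before the data were examined were Leiden resolutions of 1 and 0.3, 15 plain neighbours with no adjustment for library, a stricter filter of 1000 UMIs and 500 genes, keeping doublets, median-of-ratios scaling, a floor of 5 CPM, thinning each cell to 1000 UMIs, and leaving out each library in turn. Clustering without the listed identifiers, removing the 5% of cells with the highest doublet score in each library, naming from the top 10 or 100 genes, the stricter filter for list levels per library, leaving out libraries for levels per library, and leaving out the most abundant member of a list or 3 identifiers of the jasmonate list were added after the data had been seen.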

Results

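The data set holds single-cell RNA counts from protoplasts of tomato leaf, from healthy plants and from plants infected with tomato chlorosis virus, a whitefly-transmitted virus that yellows leaves between the veins. After filtering, 43083 of 44867 barcodes were kept as cells in 5 libraries. Libraries 1 to 5 held 12870, 6000, 7000, 8573 and 8640 kept cells. Their kept counts came to 25839218, 13657217, 9944807, 39329508 and 25567928 UMIs. The median cell held 1635, 2098, 1223, 2862 and 1990.5 UMIs in the same order. The 1784 barcodes left out carried 0.675% of all UMIs. Libraries 2 and 3 contained exactly 6000 and 7000 barcodes, and their shallowest barcodes held 1527 and 671 UMIs, against 340, 307 and 500 UMIs in libraries 1, 4 and 5. The comparison of infected with healthy leaves that the labels imply could not be made, because the cells of this matrix carry no link to the labelled samples.

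The first question was which leaf cell types the libraries contained. The cells formed 9 clusters, 2 of which could be named. Cluster 3, with 5538 cells, was mesophyll-like. There, 3 of the 10 mesophyll identifiers, which stand for the photosynthetic tissue of the leaf, were at least 2-fold higher in every library. These 3 were the carbon fixation identifiers. Of the 7 light harvesting identifiers, 4 had a median ratio above 0 in cluster 3, but 0 were higher in every library. Cluster 6, with 3744 cells, was epidermis-like, with 4 of 9 identifiers of the outer cell layer at least 2-fold higher in every library. The members of the epidermis list with a mean of 1 CPM or more had a median log2 ratio of 5.18 in cluster 6. This list gave the cluster its name, so that value is not a separate finding about it. As a summed level, however, the epidermis list was also higher in cluster 3 than in other cells in 4 of 5 libraries. A single identifier, Solyc10g075150, made up 97.7% of that sum in cluster 3, and its median log2 ratio in cluster 2 was 2.02. In cluster 6 this identifier was lower in every library, at a median of -2.60 (range -2.68 to -1.46), and so went against the name. The remaining 7 clusters stayed unnamed. Cluster 2 nevertheless shared part of the mesophyll profile. Its 3 carbon fixation identifiers were also higher in every library, at median log2 ratios of 1.29, 1.17 and 0.89, but not 2-fold in every library. Of the 10 mesophyll identifiers, 7 had a median above 0 in cluster 2 and 1 below. The lack of a name therefore does not mean that cluster 2 held no mesophyll cells. No guard cell or trichome identifier reached a mean of 1 CPM, so those cell types could not be recognised.

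Mesophyll-like cells made up 28.6% of library 1 (95% interval 27.8 to 29.4), 1.08% of library 2 (0.837 to 1.38), 3.24% of library 3 (2.84 to 3.68), 10.8% of library 4 (10.2 to 11.5) and 7.38% of library 5 (6.84 to 7.96). Epidermis-like cells made up between 5.52% and 11.3% of a library, with a median of 7.64%. The 2 largest clusters, 1 and 2, had no class and held 11924 and 9923 cells. Their median shares over the libraries were 27.7% and 23.9%. Protoplasting, the fixed barcode numbers of libraries 2 and 3 and the different depth floors can each set such shares. The boundary between cluster 3 and clusters 1, 2 and 4 moved with the clustering: the median share of mesophyll-like cells over libraries, 7.38% in the main clustering, ran from 3.92% at resolution 1 to 39.7% without adjustment for library.

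**Figure D1:**
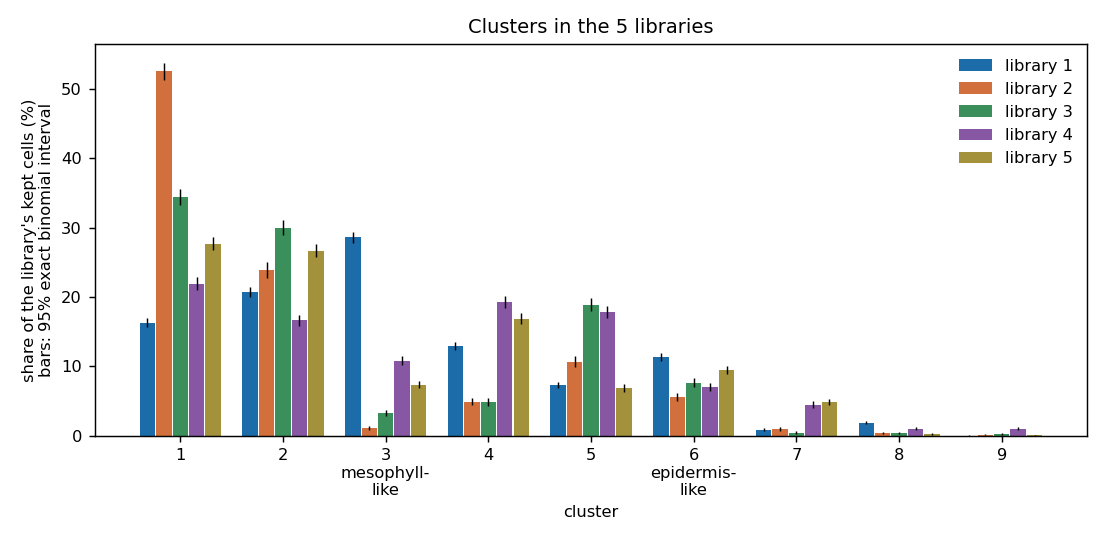
Share of each library's kept cells (percent, vertical axis) in the 9 clusters (horizontal axis), with 1 bar per library and 95% exact binomial intervals. Cluster 3, mesophyll-like, held 28.6% of library 1 and 1.08% of library 2, while cluster 6, epidermis-like, stayed between 5.52% and 11.3%.

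The next question was how the fixed gene groups were distributed over the clusters. Genes of chlorophyll metabolism followed the mesophyll-like cells. The chlorophyll synthesis list was higher in cluster 3 than in the other cells of the same library in 5 of 5 libraries, with a median log2 ratio of 2.03 (range 1.57 to 3.50), and 3 of its 8 members were at least 2-fold higher in every library. The chlorophyll breakdown list was also higher there in 5 of 5 libraries, with a median log2 ratio of 1.15 (range 0.42 to 1.49). Members of the 2 chlorophyll lists had medians above 100% and 99.8% of random lists of matched level. The summed level of the 3 reactive oxygen identifiers was higher in 5 of 5 libraries too, at 1.92 (range 0.07 to 2.65), but its members differed. In cluster 3, 1 of them made up 86.1% of the sum and was lower in at least 1 library, 1 was at least 2-fold higher in every library, and 1 was lower in every library, at a median of -1.66. Cluster 2 showed the same lists at smaller ratios, each higher in 5 of 5 libraries: 1.26 for chlorophyll synthesis, 0.96 for chlorophyll breakdown and 1.34 for the reactive oxygen sum, of which 1 member was again lower in every library, at -1.33. The light harvesting and carbon fixation lists share all of their identifiers with the mesophyll list used for naming. Their levels in cluster 3 (median log2 ratios of 2.22 and 2.41) are therefore not separate findings about it. In library 2 the light harvesting list had 0 UMIs in the 65 cells of cluster 3, which, at the upper limit of 3 counts, allows up to 23.8 CPM. Without adjustment for library, the cluster that overlapped cluster 3 most held at least 50 cells in 1 library, and each of these 5 lists was higher there in that library.

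In cluster 5, with 5018 cells, RNA silencing genes stood higher and pathogenesis-related genes lower than in other cells. The summed levels of these lists also did so in the smaller clusters 7, 8 and 9. RNA silencing degrades viral and other RNAs through small RNAs, and its list was higher in cluster 5 than in other cells in 5 of 5 libraries, with a median log2 ratio of 0.58 (range 0.50 to 1.08). Of the 15 members with a mean of 1 CPM or more, 14 had a median ratio above 0 and 11 were higher in every library. The median member stood at 1.08, above 99.98% of matched random lists. Of these members, 3 were at least 2-fold higher in every library, at 9.49, 12.7 and 17.0 CPM, below the 50 CPM asked of genes counted as higher in a cluster. The pathogenesis-related list, made of secreted defence proteins such as chitinases and glucanases, was lower in cluster 5 in 5 of 5 libraries, with a median log2 ratio of -1.44 (range -2.01 to -0.67). Of its 14 members at that level, 10 had a median ratio below 0 and 3 above, while 5 were lower in every library and 0 were higher. At least 2-fold lower in every library was 1 of them. The most abundant member, with 21.7% of the sum, was not lower, at a median of 0.06 (range -0.38 to 0.63). The median member, at -0.62, stood above 0.06% of random lists. Carbon fixation and chlorophyll synthesis were lower in cluster 5 in all 5 libraries, with median log2 ratios of -2.18 and -0.89. With median-of-ratios scaling the RNA silencing ratio was 0.30, still higher in 5 of 5 libraries. The RNA silencing sum was also higher in cluster 3 in 5 of 5 libraries, at 0.48, but its members were divided there. Of the 15, 7 had a median above 0 and 8 below, 2 were higher in every library, and 1 made up 42.2% of the sum. In clusters 1 and 4 the sum was lower in 5 of 5, at -0.60 and -0.76.

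Cluster 5 had no class of its own. In it, 110 genes were at least 2-fold higher in every library, led by Solyc03g097870 (629 CPM in cluster 5 against 8.83 CPM in other cells) and Solyc03g097590 (78.4 against 1.26 CPM). Of the 4 phloem and 2 dividing-cell identifiers, 1 each was at least 2-fold higher in every library, at 11.8 and 32.9 CPM, so neither is among the 110. The files do not pair these identifiers with gene names. Cluster 5 took between 6.85% and 18.9% of a library, with a median of 10.6%.

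The pathogenesis-related list also varied among the other clusters. It was higher in cluster 3 in 5 of 5 libraries, at a median log2 ratio of 0.69 (range 0.05 to 1.10), but 0 of its 14 members were at least 2-fold higher in every library, 1 was lower, and the list was higher in 3 of 5 libraries with median-of-ratios scaling. In cluster 8 it was lower in both libraries that had at least 50 cells, at -2.10. The summed level of the 2 ethylene identifiers was lower in the epidermis-like cluster in 5 of 5 libraries, at a median log2 ratio of -1.36 (range -2.38 to -1.07), and higher in cluster 1 in 5 of 5, at 0.59 (range 0.49 to 1.31). These sums describe 1 identifier, which made up 93.0% and 97.8% of them. The other had, in the same order, medians of -0.45 (range -1.31 to 0.29) and -0.32 (range -1.93 to 0.13). The sum was lower in cluster 5 as well, in 5 of 5 libraries (range -1.61 to -0.49), and in every library compared in clusters 7, 8 and 9. The median log2 ratios of the jasmonate and salicylate lists lay between -0.46 and 0.19 and between -0.90 and 0.27. The lowest salicylate value came from cluster 8, with 2 libraries. The jasmonate list had its highest median in cluster 2, where it was higher in 4 of 5 libraries, and that median turned from 0.19 to -0.023 with median-of-ratios scaling. Before that scaling, 13 of its 19 members had a median above 0 in cluster 2 and 6 below. Of the 19, 8 were higher in every library, 1 of them at least 2-fold and above 50 CPM, and 2 were lower in every library. The single sugar metabolism identifier with a mean of 1 CPM or more was higher in the epidermis-like cluster in 5 of 5 libraries, at a median of 0.63. The housekeeping sum had medians between -0.44 and 0.14 in clusters 1 to 6, but its members were not flat in clusters 3 and 5. In cluster 3, 5 of 6 members had a median above 0, and 3 were higher in every library, at medians of 0.45 to 0.57. In cluster 5, 4 of 6 were above 0, and 3 were higher in every library, at medians of 0.35 to 0.83. There, 1 member was lower in every library, and another made up 68.8% of the sum. In the small clusters 7, 8 and 9 the housekeeping sum stood at -0.40, -0.38 and 0.75, with 6 of 6 members below 0 in cluster 7 and 5 of 6 above 0 in cluster 9.

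**Figure D2:**
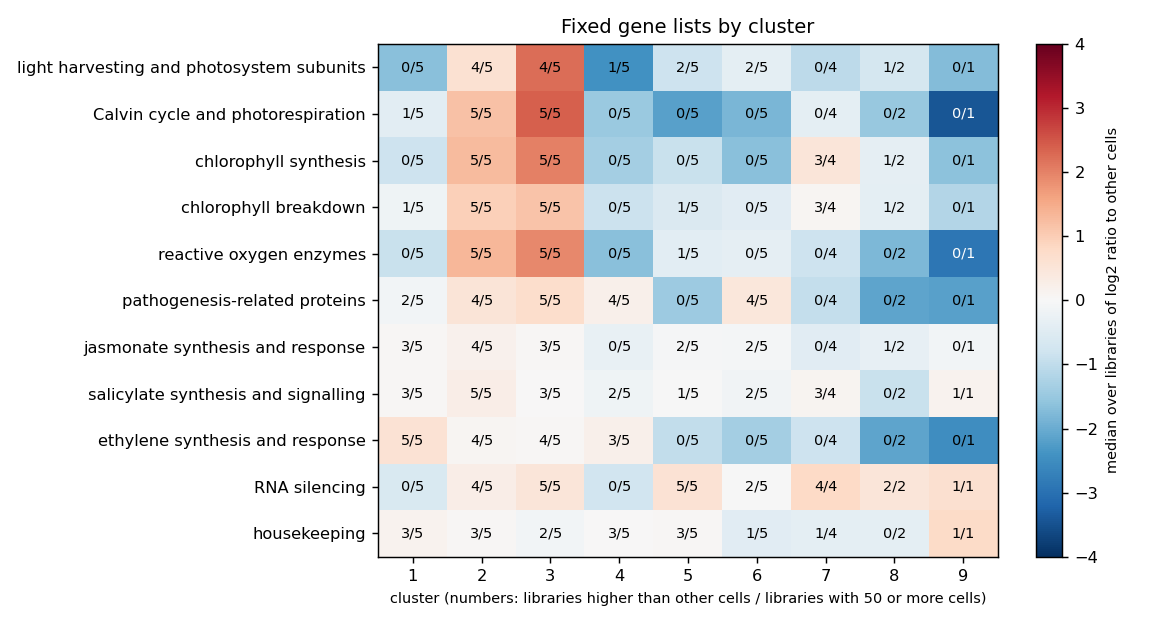
Median over libraries of the log2 ratio of each list's summed level in a cluster to that in the other cells (colour), for 11 lists (rows) and 9 clusters (columns), with the number of libraries in which the list was higher out of those with at least 50 cells written in each field. Chlorophyll lists peak in cluster 3, and RNA silencing is higher and pathogenesis-related proteins are lower in cluster 5 in 5 of 5 libraries and in every library compared in clusters 7, 8 and 9.

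Among the small clusters, cluster 8 (394 cells) carried phloem identifiers and cluster 9 (130 cells) dividing-cell identifiers. In cluster 8 the phloem list stood at a median log2 ratio of 2.57 over 2 libraries, with 2 of 4 identifiers at least 2-fold higher in both, RNA silencing was higher in both, at 0.49, and Solyc08g082190 reached 37568 CPM against 40.7 CPM in other cells. In cluster 9 both dividing-cell identifiers were at least 2-fold higher, at 154 and 45.4 CPM, in the 1 library with at least 50 of its cells, library 4. RNA silencing stood at 0.64 and pathogenesis-related genes at -2.16 there, below the housekeeping ratio of 0.75. A name needed 3 identifiers, which the dividing-cell list, with 2, cannot supply. Cluster 7 (1008 cells) was shallow, with a median of 995 UMIs. The RNA silencing sum was higher there in 4 of 4 libraries, at a median log2 ratio of 0.78, with a median above 0 for 11 of 15 members. Only 2 members were higher in every library, 1 was lower in every library, and 1 made up 32.7% of the sum. Cluster 2 likewise had 11 of 15 members above 0 and 2 higher in every library. Pathogenesis-related genes were lower in cluster 7 in 4 of 4, at -0.94, with 14 of 14 members below 0. Cluster 4 was deep, with a median of 3576 UMIs, and 3 genes were at least 2-fold higher in every library.

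The last question was how far the summed levels of the gene groups ranged over the libraries, which are given as values and not as groups. The widest ranges over all 5 libraries were those of photosynthesis lists, and they were narrower without library 1. The light harvesting list, the antenna proteins of the chloroplast, stood at 1870, 2.27, 27.8, 187 and 4.07 CPM in libraries 1 to 5, an 824-fold range (95% interval 580 to 1213). The chlorophyll synthesis list stood at 655, 7.47, 42.7, 102 and 10.2 CPM, an 87.7-fold range, and the carbon fixation list at 6702, 108, 439, 571 and 81.4 CPM. Without library 1 the ranges of the light harvesting, chlorophyll synthesis and carbon fixation lists were 82.3-fold, 13.6-fold and 7.01-fold, and without library 2 the light harvesting range was 460-fold. The carbon fixation range over all libraries was 82.3-fold, and 735-fold without its most abundant identifier. Scaling by median-of-ratios size factors, which moved all genes of a library by between -0.51 and 0.52 on the log2 scale, gave 406-fold for light harvesting and 43.2-fold for chlorophyll synthesis.

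Defence-related lists are given next. Pathogenesis-related genes stood at 509, 488, 1591, 1332 and 4350 CPM in libraries 1 to 5, an 8.91-fold range that became 3.26-fold without library 5 and 14.4-fold with median-of-ratios scaling. RNA silencing genes stood at 381, 179, 379, 214 and 170 CPM, a 2.25-fold range. Jasmonate genes stood at 18111, 6556, 9996, 8630 and 5632 CPM, a 3.22-fold range that became 1.77-fold without library 1, 1.86-fold without 3 identifiers that were high in library 1, and 1.91-fold with median-of-ratios scaling. Salicylate genes lay between 41.9 and 202 CPM with a median of 86.7, ethylene identifiers between 1556 and 6669 with a median of 2485, chlorophyll breakdown genes between 93.2 and 421 with a median of 206, reactive oxygen enzymes between 243 and 1691 with a median of 844, and sugar metabolism identifiers between 225 and 636 with a median of 332. Housekeeping genes, between 1203 and 2185 CPM, had a 1.82-fold range. Among all genes, 3724 of the 4196 that reached 50 CPM in a library differed at least 2-fold between their highest and lowest library.

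**Figure D3:**
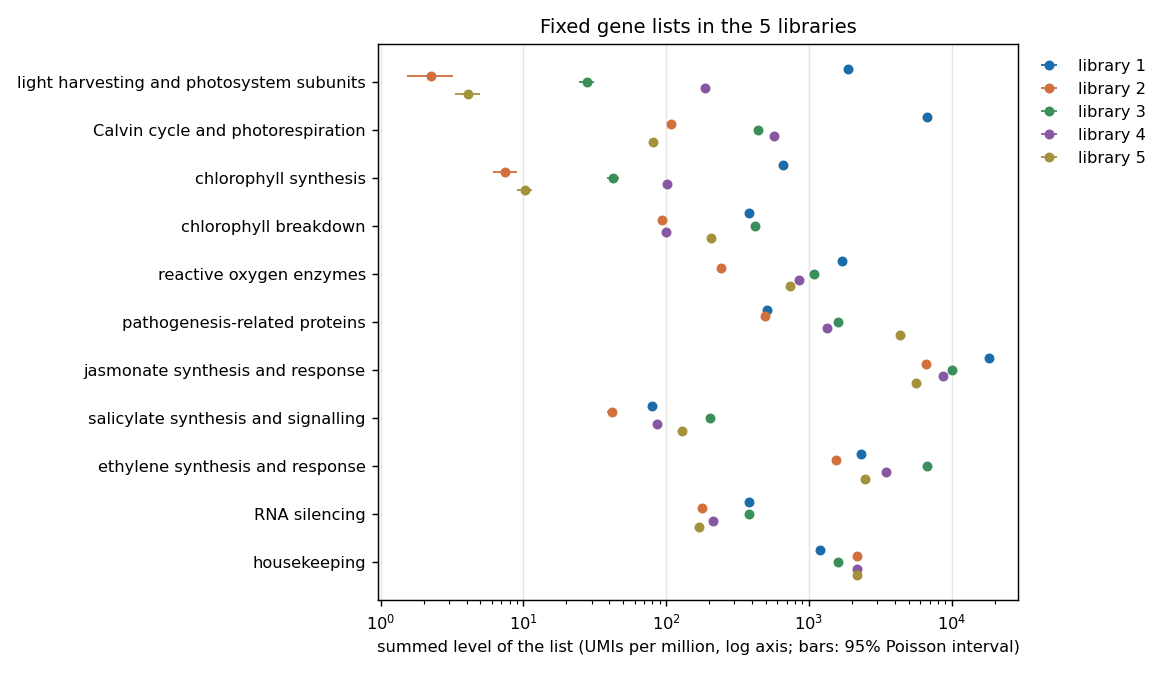
Summed level of 11 fixed gene lists (rows) in CPM on a log axis, with 1 point per library and 95% Poisson intervals for counting error. The light harvesting list runs from 2.27 to 1870 CPM, while the housekeeping list stays between 1203 and 2185.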

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

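Clustering without the listed identifiers, removing high doublet scores, naming from the top 10 or 100 genes, and the stricter filter, left-out libraries or left-out list members for levels per library were chosen after the data had been seen. No paired analysis was possible because nothing ties the cells to a labelled sample. Keeping doublets equals the main analysis, in which none were removed, and a floor of 5 CPM has no effect on sums of lists. The cause of the changes below was not tested unless stated. Clusters 5, 6 and 8 were found again in most settings, with a median overlap (Jaccard) of 0.851, 0.895 and 0.922 and a lowest of 0.369, 0.373 and 0.0319. Clusters 1 to 4 had median overlaps of 0.452, 0.395, 0.373 and 0.330, and clusters 7 and 9 had 0.0632 and 0.0273. Higher RNA silencing and lower pathogenesis-related levels in cluster 5, and a lower summed ethylene level in cluster 6, held in every library compared under each alternative run.

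The 9 clusters became 5 at resolution 0.3 and 15 without adjustment for library. The median share of mesophyll-like cells, 7.38%, became 3.92% at resolution 1, 25.8% at 0.3, 39.7% without adjustment, 28.1% with the stricter filter, 31.3% without listed identifiers, 27.2% without high doublet scores, and 8.93% to 25.5% with 1 library left out. That of epidermis-like cells, 7.64%, became 6.91% with the stricter filter and 6.83% to 8.88% with 1 library left out.

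Without adjustment for library, clusters followed libraries, so fewer libraries held 50 cells of the cluster matched. RNA silencing was then higher in 3 of 3 libraries and pathogenesis-related genes lower in 3 of 3 (cluster 5), and ethylene was lower in 2 of 2 (cluster 6). Light harvesting, carbon fixation, chlorophyll synthesis, chlorophyll breakdown and reactive oxygen enzymes (cluster 3) and jasmonate (cluster 2) were each higher in 1 of 1. Pathogenesis-related genes in cluster 3 and salicylate in cluster 2 were higher in 0 of 1, with log2 ratios of -0.19 and -0.018. With median-of-ratios scaling, pathogenesis-related genes were higher in cluster 3 in 3 of 5 libraries and jasmonate in cluster 2 in 2 of 5, with a median log2 ratio of -0.023. Salicylate was higher in cluster 2 in 3 of 5 at resolution 0.3 and with the stricter filter. With 1 library left out, these counts lay between 3 and 4 for the cluster 3 lists and salicylate and between 2 and 4 for jasmonate, whose median ran from -0.057 without library 2 and -0.017 without library 5 up to 0.188.

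The range over libraries became 406-fold (light harvesting), 43.2-fold (chlorophyll synthesis), 14.4-fold (pathogenesis-related), 1.70-fold (RNA silencing) and 1.91-fold (jasmonate) with median-of-ratios scaling. Thinning gave 9.23-fold for pathogenesis-related and 3.15-fold for jasmonate genes, and the stricter filter 3.28-fold for jasmonate. Jasmonate had 1.86-fold without 3 identifiers high in library 1. Without its most abundant member the range was 7.51-fold (pathogenesis-related) or 3.75-fold (jasmonate). It rose from 82.3-fold to 735-fold for carbon fixation (95% interval 609 to 895) and from 4.81-fold to 14.6-fold for salicylate (11.4 to 19.1). For chlorophyll synthesis and RNA silencing it was 82.6-fold and 2.26-fold. For light harvesting the same step left 3 UMIs in library 2, the floor, so its 3843-fold (95% interval 1315 to 18636) is no measured range. With 1 library left out the ranges were 82.3 to 824, 13.6 to 87.7, 3.26 to 8.91, 2.13 to 2.25 and 1.77 to 3.22. At a floor of 5 CPM, where more genes are counted, 11611 genes had a 2-fold range instead of 3724, and 433 and 121 genes instead of 110 and 56 were 2-fold higher in clusters 5 and 6. Of the values of main results under the alternatives, 168 stayed within their error or within 1.5 times their count, and 69 moved. Among the values of lesser results, 155 stayed, 28 moved and 5 reversed. Thinning left out 3403, 0, 2071, 1625 and 1979 cells of libraries 1 to 5. Lists near the floor, such as light harvesting in library 2 with 31 UMIs, are limited by depth.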

Other observations

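The identifiers of 8 of the 13 lists with 3 or more members at a mean of 1 CPM moved together over the clusters. Their membership could not be checked against names, and the correlations do not check it. The 8 are not separate lists, because the light harvesting and carbon fixation identifiers make up the mesophyll list. Over 37 sums of counts by library and cluster, with each gene centred within its library, the median correlation between members was 0.90 for carbon fixation, 0.74 for chlorophyll synthesis, 0.71 for light harvesting, 0.66 for mesophyll, 0.62 for epidermis, 0.57 for chlorophyll breakdown, 0.34 for RNA silencing and 0.32 for pathogenesis-related proteins. For these 8 lists it was above 99.96% or more of random lists of matched level. The phloem list (0.33, above 89.2% of random lists) and the housekeeping list (0.25, above 96.8%) were less clear. Jasmonate (0.09, above 82.3%) and salicylate (0.08, above 55.0%) identifiers did not stand apart from random lists, and the 3 reactive oxygen identifiers went against each other (-0.51, above 0.79%). These correlations are across sums that share libraries and are not independent. Of the 122 listed identifiers, 39 were among the variable genes from which the clusters were drawn. The random lists were matched on level and not on such use. A high percentile can therefore follow in part from how the clusters were made.

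Library 1 stood apart from the others. The Pearson correlation across genes of its log2 levels with those of libraries 2 to 5 was 0.35, 0.48, 0.55 and 0.42, while the other 6 pairs lay between 0.74 and 0.84. Genes are not independent replicates, so these values only describe the libraries. Of the 10 genes with the widest range over libraries, 9 were highest in library 1. The widest range belonged to Solyc09g084470, a member of the jasmonate list, with 5313 CPM in library 1 and at most 2.03 CPM in the others.

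Of the tests below, the one on shared barcodes was chosen after its result had been seen. The libraries belong to no group, so no biological explanation was tested for any of the 3 patterns.

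The first pattern is the level of 3 identifiers of the jasmonate list, Solyc09g084470 and its neighbours in number, in library 1. A different mix of the clusters as drawn does not account for it. Within cluster 3 alone their summed level in library 1 was 16242 CPM, which is 937 times the highest level among the other libraries. Free RNA spread evenly over all droplets of library 1 does not account for it either, because the level in that library's highest cluster was 21.2 times that in its lowest, 766 CPM in cluster 4. A contribution of free RNA to the lower levels stays open, as does any difference between plants or their handling.

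The second pattern is the wide range of the light harvesting list over the libraries. When all libraries were held to cells of at least 1527 UMIs, the range was 863-fold, which is 1.05 times the range in all kept cells, so the different depth floors do not account for it. A different mix of the clusters as drawn does not account for it either. Within cluster 3 the level ran from 17.4 CPM in library 5 to 4414 CPM in library 1. This 254-fold range leaves out library 2, where no UMI of the list was counted. Neighbours were taken equally from each library, so a library with few mesophyll cells could still place other cells in cluster 3. The range within it therefore cannot settle whether the libraries differed in mesophyll content. Because the borders of cluster 3 move with the clustering, the kind of mesophyll cell captured from each leaf also stays open.

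The third pattern is the number of suffixes, 5 for 4 labelled samples. If 2 suffixes were 1 library sequenced or counted 2 times, they would share most of their barcodes. The highest share was 0.516% of the smaller set, 49 barcodes between libraries 1 and 4, which argues against this. Whether 1 sample was made into 2 separate libraries, or 1 library belongs to no labelled sample, stays open.

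By share of a cluster's own cells, clusters 8, 2 and 9 led among the 5% with the highest doublet scores. Their shares were 10.4%, 8.27% and 7.69%, while cluster 4, the deepest of the clusters with over 1000 cells, had 2.5%. By number of such cells, clusters 2, 1 and 5 led, with 821, 604 and 282.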
